A study of Daphnia magna with 48 samples.

How the data were processed

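Whole bodies of the water flea Daphnia magna, a small freshwater crustacean used in toxicity testing, were profiled by RNA sequencing after exposure to copper, arsenic, a mixture of both, or neither. The labels give exposures of 1, 2 and 4 days and 4 libraries per treatment and day, 48 libraries in 12 groups. Doses, age and the number of animals per library are not given in the sources used here. Nothing in the labels says that the 4 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

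The deposited table holds 1 count per gene and library. Per the submitters' processing notes, TopHat2 2.1.1, HTSeq and edgeR were used; the notes give no role or order for them, and the genome build, annotation and strand setting are not given in the sources used here. Per the file headers the table has 48 library columns, each named as a library title in the labels. The deposited table is named as normalised, but its values behaved as unscaled counts of reads. All values were whole numbers, and the library totals ran from 7.93 M to 20.1 M (M, mega), a 2.53-fold range. Rescaling counts and rounding them leaves regular gaps and pile-ups among low values. A score of that pattern reached at most 4.45 in the libraries as deposited, against at least 8.75 after the same counts were multiplied by 0.95 and rounded. Each of the 16066 rows had over 1 CPM in at least 3 libraries, where the lowest third-highest value of a row was 1.002 and the lowest fourth-highest was 0.133. The table is therefore a filtered one, and genes under that level were not analysed here. The design fixed before the data were examined had assumed normalised values tested with limma and had named edgeR's quasi-likelihood test as the replacement for raw counts; that replacement was used as the main test.

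The identifiers, all of which start with Dapma7bEVm, matched 0 entries of the reference gene table, which belongs to assembly ASM2063170v1.1. No gene was therefore given a name, function or location, and the gene lists fixed beforehand (metallothioneins, metal transport, heat shock, glutathione, moulting, yolk and others) could not be tested. The fixed rule for that case was to name, per exposure, the 2 genes that rose most and the 2 that fell most. It was applied within each comparison, among genes past the threshold. Without names, genes that share reads with a near-identical copy or an overlapping gene could not be marked, so any single gene reported here carries that uncertainty.

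A gene was tested when it had at least 14 counts, which is 1 CPM at the median total of 13.3 M, in at least 4 libraries; 15813 genes passed and 253 were left out. Counts were analysed with edgeR 4.0.16 in R 4.3.3. TMM scaling factors, a model of the 12 groups over all 48 libraries and the quasi-likelihood F test (two-sided) were used, with Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 23.5%, the residual degrees of freedom were 36 and the prior degrees of freedom 5.08. Levels are given as counts per M counts of the library (CPM) after TMM scaling, as mean ± SD of 4 libraries, and changes as fitted log2 fold changes with their standard errors (SE). Folds in the text are the fitted ones, which use a prior count of 0.125. A count of 0 allows up to 3 counts, which is 0.15 CPM in the deepest library and 0.378 CPM in the shallowest. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

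Comparisons were each exposure against the controls of the same day, the exposures against each other within a day, the departure of the mixture from the sum of copper and arsenic effects on the log2 scale, each exposure's effect on day 4 against that on day 1, and controls of days 2 and 4 against day 1. These made 26 comparisons. Mean scores of gene sets were compared by two-sided exact permutation tests, which for 4 against 4 libraries cannot go below 0.0286.

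The steps were tested on simulated data. In counts of 15813 genes simulated for copper against control on day 4, with 50 genes changed at each size, 32% of the 1.5-fold, 66% of the 2-fold, 84% of the 4-fold and 92% of the 8-fold changes were called. Of 145 calls 8 were unchanged genes and 0 had the wrong direction, and a simulated day 2 with no changed gene gave 0 calls. Each simulated count was drawn independently, without structure shared by libraries. In the real data other groupings of day-1 libraries called up to 1825 genes, so these rates do not give the share of false calls there. No 2 libraries of a group agreed within sampling noise; chi-square per degree of freedom of the 72 pairs was 10.1 or more.

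Alternatives fixed beforehand were no filter, DESeq2 size factors in place of TMM, the libraries of a day alone, the replicate number as a block, and leaving out each library in turn. The planned pseudocounts belong to a log-scale test and were not run. Chosen after seeing the data were the DESeq2 1.42.0 Wald test, limma 3.58.1 (limma-trend), and leaving out 3 day-4 libraries that shared a set of 10 high genes. DESeq2 left some adjusted p-values blank through its own filter, and these stayed blank.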

Results

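Gene expression was measured in 48 whole-body libraries of Daphnia magna, 4 for each of control, copper, arsenic and the mixture after 1, 2 and 4 days. The total count per library ran from 7.93 M to 20.1 M (M, mega), with a median of 13.3 M. The shallowest library and the deepest were both mixture libraries of day 2. Among 15813 tested genes, the median SE of a log2 fold change was between 0.232 and 0.233 for copper and for arsenic against control on every day.

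Day of sampling separated the libraries more than treatment did. The first 2 principal components held 15.24% and 8.716% of the variance. Day accounted for 42.3% and 63.8% of the variance along them, and treatment for 1.74% and 7.06%. Treatment was pooled over days for these shares, so an effect confined to 1 day counts partly toward day. On the second component the mixture libraries of day 2 lay at −51.84, −40.54, −26.32 and −28.07. The other libraries of day 2 lay from −31.81 to 1.78. Control replicate 4 of day 1 was the library least correlated with the others (median r across genes 0.936) and had 479 genes with no count, against 54 to 149 in the other controls of that day.

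**Figure D1:**
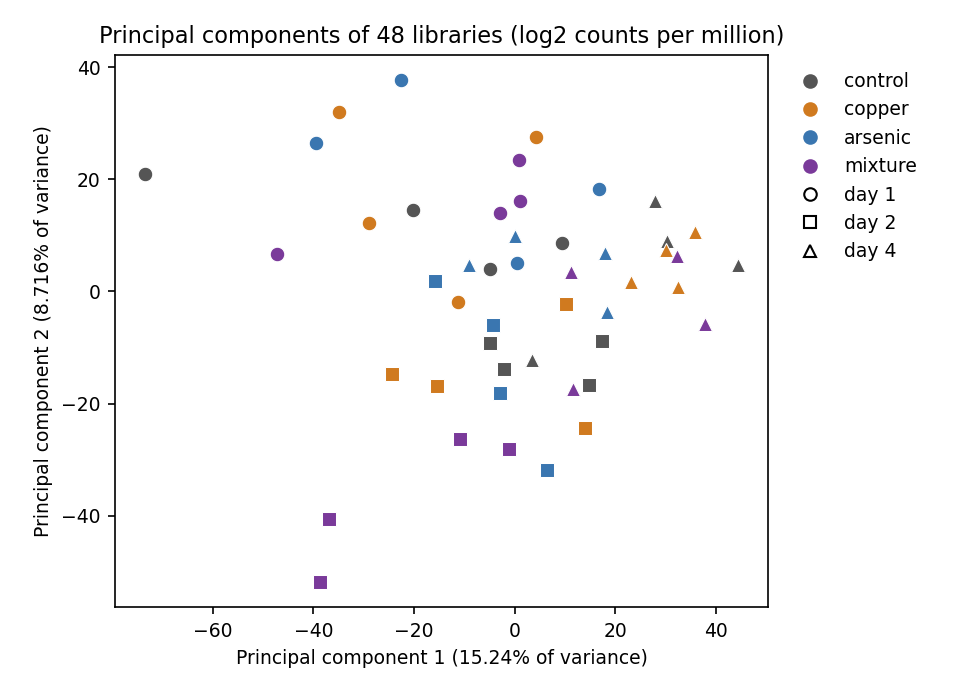
Positions of the 48 libraries on the first 2 principal components of log2 CPM (x axis, component 1, 15.24% of variance; y axis, component 2, 8.716% of variance), with colour for treatment and symbol shape for day. Libraries separate by day more than by treatment pooled over days, with day accounting for 63.8% of the variance along component 2. The mixture libraries of day 2 lie from −51.84 to −26.32 on component 2, and the other libraries of that day from −31.81 to 1.78.

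In unexposed animals, expression moved strongly over the sampling period. Dapma7bEVm001803t1 rose from 14.4 ± 2.57 CPM on day 1 to 153 ± 36.7 CPM on day 2 (log2 fold change 3.40, SE 0.37, edgeR adjusted p 6.51e-08). Dapma7bEVm006082t1 rose from 82.6 ± 18.5 to 817 ± 118 CPM (3.31, SE 0.24, adjusted p 1.16e-12). Dapma7bEVm002161t1 fell from 226 ± 46.6 to 24.3 ± 15.4 CPM (−3.23, SE 0.84, adjusted p 0.0412). The exposed groups showed no such fall in this gene. With copper, arsenic and the mixture its means were 148.2, 148.4 and 209.3 CPM on day 1. On day 2 they were 151.9, 232.5 and 192.3 CPM (SD 82.45, 148.2 and 147.8). Dapma7bEVm016118t1 fell from 2.63 ± 2.096 to 0.449 ± 0.161 CPM (−2.56, SE 0.67, adjusted p 0.0411). In all, 179 genes differed between days 1 and 2 in controls, 146 higher and 33 lower on day 2. Without control replicate 4 of day 1 the count was 72, and Dapma7bEVm002161t1 and Dapma7bEVm016118t1 had adjusted p of 0.141 and 0.391 (ranges over alternatives 0.00472 to 0.141 and 0.00593 to 0.391).

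Between days 1 and 4, 1423 genes differed in controls, 718 higher and 705 lower, and 287 of these changed more than 2-fold. Dapma7bEVm011709t1 had no count in any control library of day 1 and 0.952 to 10.8 CPM in the 4 of day 4 (adjusted p 4.05e-04). Dapma7bEVm002847t1 fell from 60.65 ± 30.02 to 8.33 ± 6.45 CPM (log2 fold change −2.85, SE 0.53, adjusted p 6.01e-04). Dapma7bEVm024676t1 fell from 0.878 ± 0.378 to 0.121 ± 0.109 CPM, near 1 count per library on day 4 (edgeR adjusted p 0.0241), and it missed the threshold in 4 of 13 alternatives (highest adjusted p 0.134). With copper, arsenic and the mixture its means were 0.3613, 0.3403 and 0.4832 CPM on day 1. They did not fall by day 4, at 0.4833, 0.7401 and 0.5818 CPM. Dapma7bEVm016693t1 was also called as higher (adjusted p 1.20e-04), but only control replicates 1 and 4 of day 4 carried it, at 96.9 and 48.3 CPM. The number of genes depended on single libraries and was 273 without control replicate 4 of day 1 and 2794 without control replicate 3 of day 1.

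Against the controls of the same day, few genes passed the threshold. The 9 comparisons gave 52 calls of 43 distinct genes, of which 8 were called more than once. About 791 of 15813 genes would have an unadjusted p under 0.05 by chance, and 6 of the 9 comparisons stayed below that number. The other 3 were the mixture on day 2 with 1737, arsenic on day 4 with 1293 and arsenic on day 1 with 930. The number of 791 takes no account of structure shared by the libraries. The libraries of each comparison can be split into 2 groups of 4 in 35 ways, the real one included. For arsenic on day 1, 21 of these splits reached 930 (highest other 4483), so that number was ordinary for these libraries. For arsenic on day 4, 3 splits reached 1293, and for the mixture on day 2 only the real one reached 1737.

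**Figure D2:**
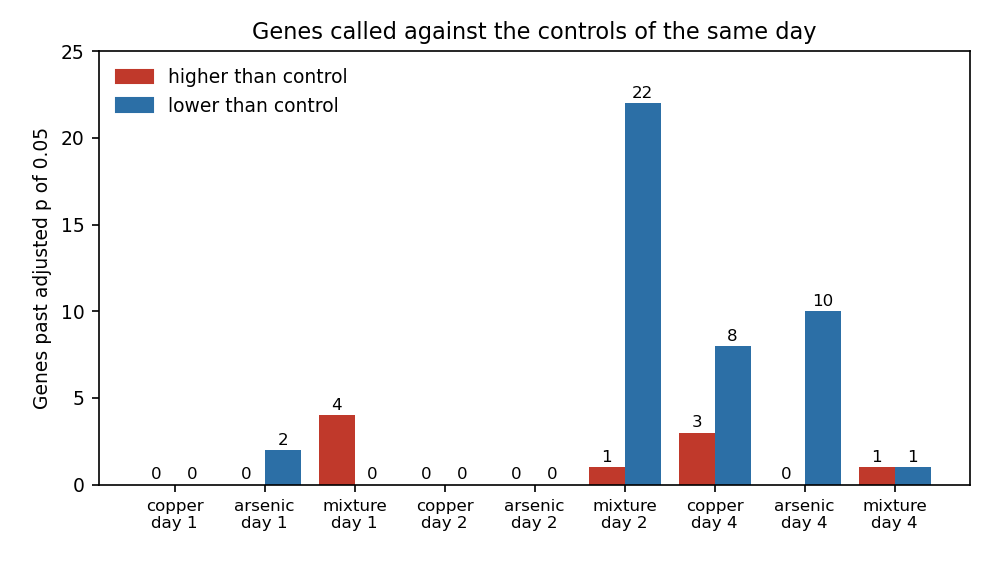
Number of genes (y axis) past an adjusted p of 0.05 in edgeR's quasi-likelihood test for each exposure and day (x axis) against the controls of that day, with 1 bar for genes higher and 1 for genes lower than control. The mixture on day 2 gave 23 genes, 22 of them lower, and copper on days 1 and 2 and arsenic on day 2 gave 0.

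Copper raised 2 genes strongly by day 4. Dapma7bEVm015179t1 stood at 4.52 ± 1.08 CPM in controls and 47.96 ± 3.39 CPM in copper libraries, a 10.6-fold rise (log2 fold change 3.40, SE 0.50, adjusted p 2.53e-04). Dapma7bEVm028938t1 stood at 6.19 ± 2.22 CPM in controls and 49.4 ± 7.15 CPM with copper, a 7.99-fold rise (2.9987, SE 0.36, adjusted p 3.75e-06). Both were higher in 4 of 4 copper libraries than in any control. On day 1 the same genes were at 7.38 ± 1.47 and 7.46 ± 1.85 CPM with copper against 2.04 ± 1.64 and 3.90 ± 1.25 CPM in controls. On day 2 they were at 10.9 ± 7.02 and 14.3 ± 7.19 CPM against 4.97 ± 1.62 and 6.95 ± 1.23 CPM, and neither day passed the test. Without control replicates 1 and 4 and mixture replicate 1 of day 4, the rise of Dapma7bEVm015179t1 was 3.22 on the log2 scale with an adjusted p of 0.176 (range over alternatives 1.48e-07 to 0.176), and that of Dapma7bEVm028938t1 was 2.79 with an adjusted p of 0.0147 (1.5e-14 to 0.0147).

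**Figure D3:**
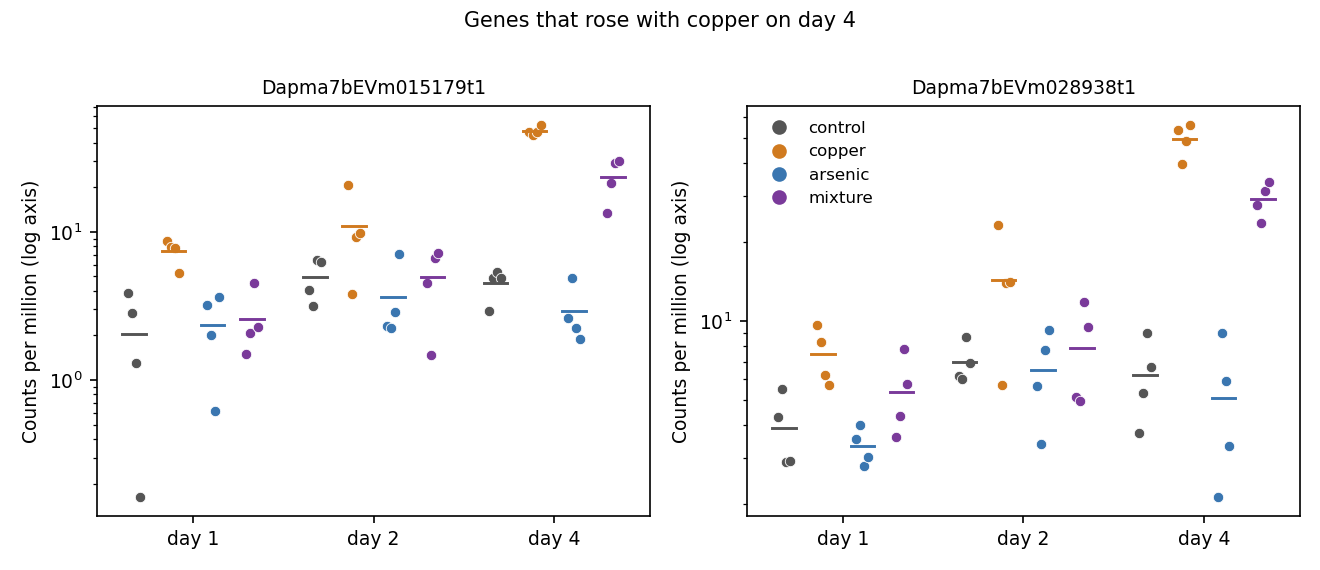
CPM (y axis, log scale) of Dapma7bEVm015179t1 and Dapma7bEVm028938t1 in each of the 48 libraries by day (x axis) and treatment (colour), with 1 point per library and a line at the group mean. On day 4 the copper libraries lie at 44.8 to 52.8 and 39.8 to 56.0 CPM, above all controls of the day.

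In all, 11 genes differed between copper and control on day 4, 3 higher and 8 lower. The largest falls belonged to Dapma7bEVm016693t1 (adjusted p 4.20e-04) and Dapma7bEVm010197t1 (log2 fold change −6.97, SE 1.20, adjusted p 0.00243). Their control means of 36.5 ± 46.2 and 78.5 ± 96.2 CPM came from control replicates 1 and 4, and the other controls reached as low as 0.0692 and 0.865 CPM. For 7 of the 11 genes both of these control libraries exceeded the 13 day-4 libraries outside the trio of control 1, control 4 and mixture 1. Without that trio 1 gene was called, Dapma7bEVm028938t1. On days 1 and 2, edgeR called 0 genes for copper, with 776 and 265 genes at an unadjusted p under 0.05. DESeq2 called 1 and 2 genes and limma 0 and 0.

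With arsenic, 2 genes were lower than in controls on day 1, though 5 of 35 splits of these libraries, the real one included, gave as many. Dapma7bEVm010823t1 fell from 23.0 ± 3.27 to 11.3 ± 1.52 CPM (log2 fold change −1.02, SE 0.16, adjusted p 0.00113), and Dapma7bEVm011979t1 from 10.7 ± 2.73 to 4.81 ± 1.47 CPM (−1.13, SE 0.21, adjusted p 0.0182). In both, the 4 arsenic libraries lay below the 4 controls. On the same day they were at 17.8 ± 2.16 and 6.29 ± 1.65 CPM with copper and at 14.6 ± 1.497 and 6.30 ± 0.881 CPM in the mixture, without passing the test there. The fall of Dapma7bEVm011979t1 had an adjusted p of 0.826 in a fit of day-1 libraries alone (range over alternatives 0.000936 to 0.826). It missed the threshold in 7 of 14 alternatives, while Dapma7bEVm010823t1 passed in 14 of 14. On day 2 edgeR called 0 genes, with 576 at an unadjusted p under 0.05, and DESeq2 and limma also called 0.

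On day 4, 10 genes were lower with arsenic than in controls and 0 were higher. Dapma7bEVm016693t1 was at 0.206 ± 0.205 CPM and Dapma7bEVm008714t1 at 0.137 ± 0.168 CPM with arsenic, and both rested on the same pair of control libraries as the falls with copper (adjusted p 0.00209 and 0.00326). This pair exceeded the 13 other day-4 libraries for 9 of the 10 genes. Without the trio 1 gene was called, with a log2 fold change of −1.30 (SE 0.23, adjusted p 0.0366). Of the falls with arsenic, 7 were also falls with copper, against the same controls.

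**Figure D4:**
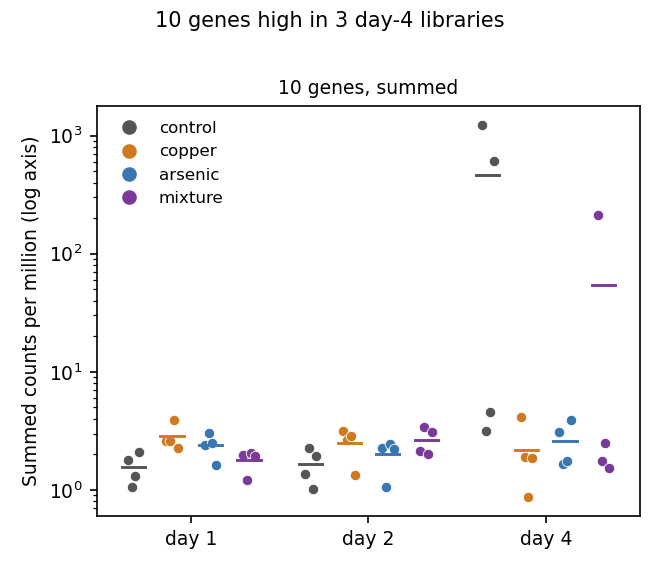
Summed CPM (y axis, log scale) of 10 genes in each of the 48 libraries by day (x axis) and treatment (colour), with 1 point per library and a line at the group mean. Control replicates 1 and 4 and mixture replicate 1 of day 4 reach 1235, 612.7 and 211.1 CPM, and no other library exceeds 4.59.

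With the mixture, 4 genes were higher than in controls on day 1, though 2 of 35 splits of these libraries, the real one included, gave as many. Dapma7bEVm002921t1 rose from 98.5 ± 24.1 to 255 ± 36.1 CPM, 2.59-fold (log2 fold change 1.37, SE 0.23, adjusted p 0.00282). Dapma7bEVm000727t1 rose from 124.3 ± 7.86 to 228 ± 13.2 CPM, 1.835-fold (0.88, SE 0.13, adjusted p 0.00123). With arsenic alone they were at 182 ± 42.5 and 193 ± 39.9 CPM (adjusted p 0.387 and 0.123), and with copper alone at 106 ± 25.3 and 139 ± 15.1 CPM (adjusted p 0.982 and 0.966). Without control replicate 4 of day 1 the mixture had 1 called gene, and Dapma7bEVm002921t1 had an adjusted p of 0.0747 (range over alternatives 1.18e-05 to 0.0747).

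On day 2 the mixture differed from control in 23 genes, 22 lower and 1 higher. Dapma7bEVm009737t1 fell from 4.53 ± 2.41 to 0.901 ± 0.301 CPM (log2 fold change −2.36, SE 0.46, adjusted p 0.0172), and Dapma7bEVm027592t1 from 3.81 ± 0.658 to 0.776 ± 0.610 CPM (−2.27, SE 0.51, adjusted p 0.0448). Dapma7bEVm006966t1 rose from 23.1 ± 1.70 to 32.6 ± 0.711 CPM, 1.42-fold (0.50, SE 0.10, adjusted p 0.0239). In the order given, these 3 genes missed the threshold in 5, 8 and 7 of 14 alternatives (highest adjusted p 0.167, 0.307 and 0.176). The median log2 fold change of the 22 lower genes was −1.52. An unadjusted p under 0.05 was found for 1737 genes. DESeq2 called 104 genes, a fit of the day-2 libraries alone called 3, and leaving out control replicate 3, mixture replicate 1 or mixture replicate 2 of day 2 left 2.

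By day 4 the mixture differed from control in 2 genes. Dapma7bEVm028938t1 was higher, at 29.1 ± 4.44 CPM against 6.19 ± 2.22 CPM in controls, 4.7-fold (log2 fold change 2.23, SE 0.35, adjusted p 0.00237). Dapma7bEVm015179t1, at 23.4 ± 7.74 against 4.52 ± 1.08 CPM, had an adjusted p of 0.0528. Dapma7bEVm016693t1 was lower (adjusted p 0.0254) and rested on control replicates 1 and 4. Without the trio of day-4 libraries edgeR called 0 genes, with 491 at an unadjusted p under 0.05, and the rise of Dapma7bEVm028938t1 was 2.05 on the log2 scale.

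Exposures were compared with each other to ask whether copper, arsenic and the mixture gave distinct responses. Copper and arsenic differed on day 4, where 12 genes were higher with copper and 0 were lower. Dapma7bEVm015179t1 was at 47.96 ± 3.39 CPM with copper and 2.90 ± 1.34 CPM with arsenic, 16.3-fold apart (log2 fold change 4.03, SE 0.52, adjusted p 1.02e-05). Dapma7bEVm017922t1 was at 2.495 ± 0.480 against 0.195 ± 0.2002 CPM (adjusted p 0.0369), and it missed the threshold in 8 of 14 alternatives (highest adjusted p 0.258). Of the 12 genes, 10 were called without the trio of day-4 libraries. Leaving out single libraries of these 2 groups gave 5 to 19 genes. On days 1 and 2 edgeR called 0 genes between copper and arsenic, with 589 and 465 at an unadjusted p under 0.05, as did DESeq2 and limma.

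The mixture was set against each metal alone on day 4. It exceeded arsenic in 3 genes, among them Dapma7bEVm028938t1 (29.1 ± 4.44 against 5.10 ± 3.05 CPM, log2 fold change 2.5007, SE 0.36, adjusted p 2.33e-04) and Dapma7bEVm015179t1 (2.9958, SE 0.50, adjusted p 0.00364). Between mixture and copper on day 4 edgeR called 0 genes, with 510 at an unadjusted p under 0.05, while DESeq2 called 1 and limma 0. The 2 genes were 0.588 and 0.490 of their copper level in the mixture, with unadjusted p of 0.0251 and 0.0275.

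On day 2 the mixture differed from arsenic in 14 genes, 13 lower and 1 higher, and 6 of them were also called against control. Dapma7bEVm016573t1 was at 0.113 ± 0.180 CPM in the mixture and 4.42 ± 1.71 CPM with arsenic (adjusted p 0.0343). Dapma7bEVm018552t1 was at 2.87 ± 1.56 against 21.5 ± 8.72 CPM (log2 fold change −2.93, SE 0.63, adjusted p 0.0400), and Dapma7bEVm001465t1 at 18.3 ± 3.41 against 9.67 ± 2.29 CPM (0.92, SE 0.18, adjusted p 0.0343). Against copper on day 2 edgeR called 1 gene, Dapma7bEVm009737t1, at 0.901 ± 0.301 against 6.80 ± 3.61 CPM (−2.94, SE 0.46, adjusted p 0.00207). DESeq2 called 30 there, limma 3, a fit of the day-2 libraries alone 0, and edgeR called 9 without mixture replicate 3, 8 without copper replicate 4, and 2 without copper replicate 3 or mixture replicate 4. On day 1 the mixture exceeded copper in Dapma7bEVm002921t1 and Dapma7bEVm000727t1 (adjusted p 0.0241 and 0.0256). They passed the threshold in 8 and 5 of 14 alternatives (highest adjusted p 0.22 and 0.3), and a fit of the day-1 libraries alone called 0. Leaving out single libraries gave 0 to 4 genes, with 0 without copper replicate 1, 3 or 4 or mixture replicate 3 or 4, 1 without copper replicate 2, and 4 without mixture replicate 1. Against arsenic on day 1 edgeR called 0 genes, with 464 at an unadjusted p under 0.05, and DESeq2 and limma 0. Leaving out arsenic replicate 1 or mixture replicate 1 of day 2 left 0 of the 14 genes called, and a fit of the day-2 libraries alone called 2.

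The mixture was also compared with the sum of the copper and arsenic effects. That sum tests additivity only if the mixture held each metal at its single-exposure dose. Doses are not given, so neither a departure nor its absence can be read as settling additivity. On days 1 and 2 edgeR called 0 departures, with 815 and 708 genes at an unadjusted p under 0.05, and DESeq2 and limma called 0. On day 4, 7 genes departed, all with a mixture level above the sum, Dapma7bEVm016693t1 and Dapma7bEVm010197t1 among them (adjusted p 0.0270 and 9.32e-04). All 7 were genes for which control replicates 1 and 4 exceeded the 13 day-4 libraries outside the trio. Without the trio edgeR called 0 departures, with 971 genes at an unadjusted p under 0.05.

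The effect of each exposure on day 4 was set against its effect on day 1 to ask whether responses grew with time. EdgeR called 0 genes for copper, arsenic and the mixture, with 494, 1104 and 605 genes at an unadjusted p under 0.05. DESeq2 called 2, 1 and 0, and limma 0 for each. For Dapma7bEVm028938t1 the copper effect was larger on day 4 than on day 1 by 2.07 on the log2 scale (SE 0.50, adjusted p 0.558), so a difference between days was not established for it.

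Fold changes of different exposures correlated across genes, as shared controls alone make them do. Pearson's r over 15813 genes, which are not independent replicates, was 0.414 to 0.61 for the 9 pairs of exposures within a day, and simulated unchanged groups gave 0.485 to 0.506. With the controls split so that the 2 exposures shared none, r was between −0.0872 and 0.116. The covariances with split controls lay within the range of shuffled labels for all 9 pairs.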

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

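The tests of explanations in this part were chosen after the results had been seen, and the counts over other splits of the libraries were planned but their tests were written down after those counts had been seen. A library was singled out when it lay far from the other 3 of its group by Dixon's criterion, which chance meets in about 1 in 20 groups. Among 48 groups tested for library measures 7 were singled out, against 2.4 by chance, and among 58 groups tested for named genes 4, against 2.9.

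On day 4, 7 genes departed from additivity, a test of whether the mixture effect differs from the sum of the copper and arsenic effects. These 7 rest on a set of libraries with unusual content. By a rule of over 80% of a gene's summed CPM in the same 3 libraries, 10 genes were found in control replicates 1 and 4 and mixture replicate 1 of day 4, at 1235, 612.7 and 211.1 CPM in sum. The highest of the other 45 libraries had 4.59 CPM. Of the 10 genes, 4 were among the 7 departures. Some of the others, such as Dapma7bEVm010785t1, were not tested because too few libraries reached the filter. A pair of named members stood out in mixture replicate 1, Dapma7bEVm010197t1 at 32.13 CPM, where the other 3 mixture libraries had at most 0.6955, and Dapma7bEVm016693t1 at 2.008 CPM, where they had at most 0.2782. Dapma7bEVm016693t1 also stood out in copper replicate 3 of day 4, at 0.1742 CPM or 2 counts, with no count in the others. Among the 560 ways to choose 3 of the 16 day-4 libraries, this trio had 16 genes apart and 4-fold higher, and the others had at most 2.

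Sequencing depth is argued against for this set, since 15 of the other 45 libraries, 3 of them of day 4, had totals between the lowest (8.84 M) and the highest (12.3 M) of the 3 libraries without this content. RNA of 1 further source with a fixed composition predicts that the 10 genes keep 1 ratio between libraries. Between the 2 control libraries the spread of the log2 ratio over the 10 genes was 1.06 times that of ordinary genes. Ordinary genes differ between libraries by more than counting error, so genes that vary together could give this as well, and it cannot single out such a source. Over the 3 libraries, the counts of the 10 genes departed from fixed proportions with a chi-square of 24.5 per degree of freedom, more than counting error gives. Between mixture replicate 1 and control replicate 1 the spread of the log2 ratio was 2.85 times that of ordinary genes. This argues against an identical source there, although the value fell to 1.35 without Dapma7bEVm016693t1. Whether exposure lowers these genes cannot be told apart from chance with 2 of 4 control and 1 of 12 exposed libraries (Fisher's exact test, two-sided p = 0.136), so a difference in the animals of these libraries, such as their stage, may also account for it and was not tested.

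Mixture replicate 1 of day 1 lay at −0.348 on an axis drawn from exposed libraries of day 1 (0) to those of day 4 (1), where the other 3 mixture libraries of that day lay at 0.18 to 0.225. It was 1 of 6 day-1 libraries below the widest gap on this axis, of 0.375. The 6 were 1 control, 2 copper, 2 arsenic and 1 mixture library. Their TMM factors, from 1.045 to 1.092, did not overlap those of the other 10, from 1.001 to 1.039. Totals of the 6 ran from 8.49 M to 15 M, and those of the other 10 from 11.4 M to 17.3 M. Depth as the whole difference is argued against, because 6 of the 10 were shallower than the deepest of the 6. That count rests on the deepest library, and the 6 reached lower totals, so a part played by depth stays open. Exposure as the whole difference is argued against, because 7 exposed libraries lay above the gap and a control lay below it. A batch or a difference in the stage of the animals may also be behind the gap, and no label bears on either.

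Other splits of day-1 libraries point to a structure of the samples. For arsenic against control on day 1, where the real split gave 2 genes, another split gave 1799, and for copper against control, where it gave 0, another gave 363. In both of these splits the libraries below the gap, with control replicate 2, formed 1 group and all others the second. For the departure from additivity on day 1, where the real split gave 0, another gave 1825, and whether it follows the same libraries was not examined.

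The other libraries singled out are given as values. Control replicate 1 of day 1 had a total of 16.7 M counts, with 11.4 M to 12 M in the other 3, and control replicate 2 of day 4 had 15.8 M, with 11.8 M to 12.3 M in the others. Genes with no count numbered 90 in control replicate 4 of day 2 (39 to 46 in the others), 89 in copper replicate 4 of day 2 (70 to 73) and 152 in arsenic replicate 1 of day 2 (60 to 75). The 10 most counted genes took 12.82% of control replicate 1 of day 4, against 14.28% to 14.42% in the others. Dapma7bEVm000727t1 stood at 136 CPM in control replicate 2 of day 1, with 119.2 to 121.3 CPM in the others.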

How the results depend on the processing

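The DESeq2, limma-trend and 3-library alternatives were chosen after seeing the data and the others before. Replacing TMM by DESeq2's size factors kept all 26 counts of genes within 1.5 times. Removing the filter did so for 24, with 17 genes for copper against control and 12 departures from additivity on day 4. The planned pseudocounts and gene-list tests were not run, because the values were counts and the identifiers carried no names. Depth sets the floor of a library, where 3 counts are 0.15 CPM in the deepest and 0.378 CPM in the shallowest. On simulated data for copper on day 4, 32% of 1.5-fold and 66% of 2-fold changes were called. This reflects depth, 4 libraries per group and their variation gene by gene together, without structure shared by libraries. The cause of the shifts below was not tested.

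With libraries of the day alone, 11 of 21 counts moved by over 1.5 times. On day 1 the mixture had 2 genes against control and 0 against copper, with 2 departures from additivity. On day 2 the mixture had 3 genes against control, 0 against copper and 2 against arsenic. On day 4 copper had 4 genes against control, all higher, arsenic 0, mixture against arsenic 22, copper against arsenic 38, and departures 0.

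DESeq2 moved 14 of 26 counts. It gave 1 gene for copper and 8 for the mixture on day 1, 2 for copper and 104 for the mixture on day 2, and 6 for the mixture on day 4. Mixture against copper had 7, 30 and 1 genes on days 1, 2 and 4, mixture against arsenic 98 and 23 on days 2 and 4, and copper against arsenic 27 on day 4. The effects of day 4 against day 1 had 2 genes for copper and 1 for arsenic, and controls of day 2 against day 1 had 300. Limma-trend moved 8: the mixture had 36 genes against control, 3 against copper and 37 against arsenic on day 2, and 5 against copper on day 1. On day 4 copper had 2 and arsenic 4 against control, mixture against arsenic 7, and departures 0.

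Without the 3 day-4 libraries that hold the 10-gene set, 5 of 11 counts moved. Against control on day 4, 1 gene was called for copper, 1 for arsenic and 0 for the mixture, departures from additivity numbered 0, and controls of day 4 against day 1 differed in 421 genes. The departure of Dapma7bEVm010197t1 turned from 10.33 to −0.2733 on the log2 scale (edgeR adjusted p 0.965, range over alternatives 7.37e-08 to 0.965). Fewer controls entered as well, and the part of each in the lost calls was not tested.

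The replicate numbers do not pair the libraries. Of 72 correlations between residuals of same-numbered libraries of a day, 13 were over 0.1, with a range from −0.293 to 0.287, and 16 of 48 libraries correlated best with their own number. With the replicate number as a block within day, 7 of 24 counts moved: arsenic on day 1 had 1 gene, copper on day 2 had 2, copper, arsenic and the mixture on day 4 had 5, 5 and 1, mixture against copper on day 1 had 1, and departures on day 4 had 1. With the block across days, controls differed in 151 genes between days 1 and 2 and 1209 between days 1 and 4.

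Leaving out single libraries moved many counts. Against control, the ranges were 1 to 4 genes for arsenic and 1 to 5 for the mixture on day 1, 0 to 2 for copper and 2 to 38 for the mixture on day 2, and 5 to 13, 6 to 11 and 0 to 9 for copper, arsenic and the mixture on day 4. For the mixture on day 2 the count was 14, 2 and 11 without control replicates 1, 3 and 4, and 2, 2, 38 and 36 without mixture replicates 1 to 4. For copper on day 4 it was 5 without control replicate 1, and 7, 7 and 6 without copper replicates 1, 2 and 4. For arsenic on day 4 it was 6 without control replicate 1. For the mixture on day 4 it was 0, 6, 7 and 1 without control replicates 1 to 4, and 9, 4, 1 and 1 without mixture replicates 1 to 4. On day 1 arsenic had 1 gene without control replicates 2 or 3 or arsenic replicates 1 or 2, and 4 without arsenic replicate 4, while the mixture had 2 without control replicate 3 or mixture replicate 2, and 1 without control replicate 4. Copper on day 2 had 2 without copper replicate 2.

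Between exposures, mixture against copper ran from 0 to 4 on day 1, 1 to 9 on day 2 and 0 to 1 on day 4, with the highest counts without mixture replicates 1, 3 and 2 of those days. On day 1 it was 0 or 1 without any single copper library or without mixture replicates 3 or 4, and on day 2 it was 2 and 8 without copper replicates 3 and 4 and 2 without mixture replicate 4. Mixture against arsenic ran from 0 to 36 on day 2 and from 1 to 6 on day 4. On day 2 it was 0 and 1 without arsenic replicates 1 and 2, and 0, 1, 36 and 28 without mixture replicates 1 to 4. On day 4 it was 1 without arsenic replicates 3 or 4 and 6 without mixture replicate 2. Copper against arsenic ran from 0 to 2 on day 2, with 2 without arsenic replicate 4, and from 5 to 19 on day 4. There it was 6, 5, 5 and 5 without copper replicates 1 to 4, and 6, 19, 5 and 5 without arsenic replicates 1 to 4.

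Departures from additivity ran from 0 to 2 on day 1 (2 without mixture replicate 1), 0 to 1 on day 2 (1 without arsenic replicate 4) and 1 to 7 on day 4, where they were 2 without control replicate 1 and 1 without mixture replicate 1. The effect of day 4 against day 1 ran from 0 to 4 for copper, with 1 and 4 without control replicates 2 and 3 of day 4, and from 0 to 6 for arsenic. The 6 came without control replicate 3 of day 4, and 1 gene without control replicate 3 or arsenic replicate 1 of day 1, or control replicate 4 or arsenic replicate 2 of day 4. Controls of day 2 against day 1 ran from 72 to 293, with 293 and 72 without replicates 3 and 4 of day 1 and 115 and 92 without replicates 3 and 4 of day 2. Controls of day 4 against day 1 ran from 273 to 2794, with 2794 and 273 without replicates 3 and 4 of day 1 and 417 and 744 without replicates 2 and 4 of day 4. Among named genes, Dapma7bEVm028938t1 passed the threshold for copper on day 4 in 15 of 15 alternatives (edgeR, DESeq2 or limma adjusted p 1.5e-14 to 0.0147) and Dapma7bEVm015179t1 in 14 of 15 (1.48e-07 to 0.176).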

Other observations

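The tests of the 12-gene and 22-gene sets in this part were chosen after the results had been seen, and the tests over other splits were planned but written down after their counts had been seen.

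The 12 genes that stood higher with copper than with arsenic on day 4 had a mean log2 level 1.39 above control with copper and 0.592 lower than control with arsenic on that day, in the libraries that had selected them. Of the 12, 3 were called for copper against control and 0 for arsenic against control. In the mixture of day 4, which took no part in the selection, all 12 were higher than in controls, the mean difference was 0.907 and 4 of 4 libraries lay above all controls (two-sided exact permutation p = 0.0286, the smallest possible, and 0.2 adjusted over 7 tests). Without the 3 day-4 libraries that hold the 10-gene set the difference was 0.961 (exact p = 0.1, the smallest possible). On day 1 the set lay 0.551 above control with copper (11 of 12 genes, 3 of 4 libraries, exact p = 0.114) and 0.21 above in the mixture (exact p = 0.514). On day 2 the differences were 0.426 with copper (exact p = 0.343), −0.133 in the mixture (exact p = 0.486) and −0.262 with arsenic (exact p = 0.171). A hypothesis is that the mixture may raise this set as copper does by day 4. The adjusted p of 0.2 cannot decide it, because the smallest possible p of 0.0286 gives 0.2 over 7 tests unless others are as low. Of the 12 genes, 1 was called against control in the mixture on day 4.

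The 22 genes lower in the mixture on day 2 also lay below control on that day with copper (mean log2 difference −0.523) and with arsenic (−0.297), each with an exact permutation p = 0.0286 and 0.114 adjusted over 8 tests. The controls of that day had helped to select the genes, so these values are not independent. On days 1 and 4 the differences ran from −0.177 to 0.141. Depth is argued against: mixture libraries had lower totals by 0.234 on the log2 scale, for which the slope of the set on depth within the 10 other groups gives a change of −0.00257 (2 SE 0.0689), against −1.56 found. In the 40 libraries outside both groups the residuals of the 22 genes correlated with each other at a mean r of 0.197, against a highest value of 0.115 in 1000 random lists matched on level, which is consistent with a set of genes that vary together whatever the exposure. A lag toward day 1 as the whole change is argued against, because in the mean of the set the highest mixture library of day 2 differed by −0.723 from the lowest of the 16 day-1 libraries (mixture 3.781 ± 0.386, day-1 controls 5.111 ± 0.235, day-2 controls 5.34 ± 0.124). An effect of the mixture on such a set is a further hypothesis, and it was not separated from such variation here.

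For 7 of the 26 comparisons 1 of 35 splits was as large, the real one, which excludes chance regrouping at a share under 0.05. This is the smallest share that 35 splits can give, and it was not adjusted for 26 comparisons. Counted at an unadjusted p under 0.05, the mixture on day 2 stayed at 1 of 35. The others had 10 for copper and 3 for arsenic on day 4, 19 for mixture against copper on day 1, 4 for mixture and 3 for copper against arsenic on day 4, and 3 for controls of day 2, so by that count chance was not excluded for them. They were the mixture on day 2 (23 genes, highest other split 0), copper on day 4 (11, 8), arsenic on day 4 (10, 8), mixture against copper on day 1 (2, 0), mixture against arsenic on day 4 (3, 1), copper against arsenic on day 4 (12, 0) and controls of day 2 against day 1 (179, 2). For copper and arsenic on day 4 the highest other split put control replicates 1, 2 and 4 with 1 exposed library, so it also set the pair with the 10-gene set apart. Most calls of these comparisons rest on that pair, so the count of splits does not show an effect of exposure there.

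For 7 other comparisons with genes called, the count of splits alone did not exclude chance. Among 35 splits, 5 were as large for arsenic on day 1 (2 genes, highest other 1799), 2 for the mixture on day 1 (4, 166), 8 for the mixture on day 4 (2, 12), 7 for mixture against copper on day 2 (1, 52) and 2 for mixture against arsenic on day 2 (14, 75). For controls of day 4 against day 1, 2 of 35 splits were as large, and the other one, which exchanged the libraries of replicate 3 between the days, gave 2284 genes against 1423. Single genes there are a separate matter: Dapma7bEVm011709t1 passed the threshold in 13 of 13 alternatives with an adjusted p and Dapma7bEVm002847t1 in 14 of 14. An exchange of these 2 libraries would change what the 1423 genes mean. On the axis drawn from exposed libraries the library of day 1 lay at 0.414, the highest of its day, and that of day 4 at 0.72, the lowest control of its day, in the order of the labels and both within the range of day 2 (0.169 to 0.788). On the first principal component they lay at 9.4 and 3.49, the order an exchange would give. On the second, where day accounted for more of the variance, they lay at 8.65 and −12.18, and the lowest day-1 library lay at −1.96. Dapma7bEVm011709t1 had 0 and 11 counts in them. Dapma7bEVm006082t1, named for its rise in controls by day 2, was at most 119.1 CPM in any day-1 library. In any day-4 library it was at least 262.2 CPM. The first component and the count of splits thus go with an exchange. The axis, the 2 genes and the day-4 library on the second component go with the labels, and an exchange stays open. Among 50 drawn splits, 5 were as large for departures from additivity on day 4 (7, 7). In the 12 comparisons with 0 genes by edgeR all 35 or all 50 splits are as large by construction, which says nothing about chance. Their highest other values were 363 for copper on day 1, 0 and 1 for copper and arsenic on day 2, 29 and 10 for mixture and copper against arsenic on day 1, and 59 for copper against arsenic on day 2. They were 0 for mixture against copper on day 4, 1825 and 27 for departures on days 1 and 2, and 1, 762 and 3 for the effects of copper, arsenic and the mixture on day 4 against day 1. Splits of day-2 libraries with 52, 59 and 75 genes and of day-1 libraries with 166 and 363 point to structure among libraries that the treatments do not follow.

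A group of 35 genes varied strongly between libraries of the same group. They were the largest correlated cluster (r over 0.8) among 92 genes with a within-group SD of at least 1 on the log2 scale, out of 10555 with a mean of at least 5 CPM. Their mean log2 CPM ran from 0.636 to 6.09, and the range within a group of 4 ran from 1.48-fold to 43.7-fold over the 12 groups. Genes chosen for spread within groups are biased toward no difference between groups, so no comparison of groups is given for them.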
